A study of Mus musculus with 8 samples.

How the data were processed

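The measurements were array comparative genomic hybridisations of 6 haploid mouse ES cell lines and 2 kidney samples against male kidney DNA. DNA was extracted with a Gentra Puregene kit and the ES cells were grown in 2i medium, per the labels' protocols. Labelling and data processing were done by commercial providers, Imagenes for the 6 arrays with the C57B/6 reference and Source Bioscience for the 2 H129 arrays, per the labels. The deposited values are log2 ratios of sample (Cy3) over reference (Cy5) per probe, and the scale and dyes follow the labels and the values. Their mean over all probes is close to 0 on every array, and the median of the autosomal probes before centring ran from -0.02 on the H129 arrays to 0.04 on the CBA kidney array. How the values of the 6 arrays with the C57B/6 reference were normalised is not given in the sources used here. For the 2 H129 arrays, the deposited values equal the fully corrected log2 ratio of the provider files at each probe (largest difference 0), which per the file headers follows a spatial correction and a normalisation between the channels. The log2 signals of the channels had medians of 12.7 (sample) and 12.6 (reference) on the array of H129 line 1. The provider files also give the GC content of each probe as a fraction, per the file headers, which was not used, since the GC content of windows was computed from the genome. Chromosome lengths in the provider files equal those of NCBIM37 (X, 166650296 bases), apart from the unplaced Y sequence (58682461 bases), which has no sequence of that name in the reference used here.

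Each array was centred on the median of its 664420 autosomal probes, with no loess or quantile normalisation. The level of a chromosome is the median over its probes (42531 on X, 688 on Y, 5719 on the unplaced Y sequence, which counts as Y by its name in the provider files). Group means were compared with an exact permutation test over all splits. An autosome counted as changed at a median of at least 0.3 in size and over 3 robust SDs of the 19 autosome medians. Segments were found by penalised least squares (PELT, penalty factor 4, at least 10 probes) after winsorising at 3 robust SDs around a running median of 21 probes, and were called at a median of at least 0.4 in size. Segments on X were called relative to the median of X, and no segments of Y are given. A call was shared with a kidney at a median of the same sign and at least 0.2 in size, with 100 circular shifts of the calls for the chance level. The correlation of HAP lines with the CBA kidney was taken in windows of 500 probes after removal of the window median. Windows of 1 Mb with at least 50 probes were tested with limma (lmFit, eBayes), 4 HAP and HTG arrays against 2 kidneys, at an adjusted p of 0.05 (Benjamini-Hochberg).

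Genes and coordinates come from the GENCODE annotation of NCBIM37, with 37310 genes. A gene was changed when a call covered a fraction of at least 0.5 of its body, and its value is the median over probes in the gene and 10000 bases on each side, with at least 3 probes. Of the listed genes, 3 were found through another symbol (Tcfcp2l1 for Tfcp2l1, Cd244 for Cd244a, Ube1y1 for Uba1y) and 0 were not found. The lists, the tests of the comparisons and the rule for named regions were fixed before the data were examined, and measures and tests chosen later are named as such where they are given. The lists were pluripotency, growth and genome guard, imprinted, strain variable, X linked, Y linked and antigen receptor segments. The rule took, per array, the 5 highest and 5 lowest autosomal calls, the 5 longest calls of a line that its kidney lacked (for H129 the 5 longest), each call of 1 Mb or more, the 5 windows with the largest differences in either direction among those past the threshold, up to 3 genes per region with a fraction of at least 0.5 inside it, and listed genes inside a call. From this set the text gives examples. Named outside the rule, after their values were seen, were calls of a single line (Crb2 on chromosome 2, Sprr2a1 on chromosome 3 and the Serpina1 genes on chromosome 12). So were genes that a segment only touches (Nlgn1, Macrod2, Anks1b) and unchanged members of the lists.

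The chromosome 3 segment was aligned with BLAST to the Y chromosome and to unplaced contigs of the reference at 90% identity or more, with 200 random segments of the same length from chromosome 3. Probe sequences were not used here, so the 60 bases at each probe position stood for them, with a match of at least 50 bases. Alternatives covered the thresholds, the segmentation, the sharing rule, the centring, the window size, the GC content and the omission of each array.

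The segmentation, the window test and the haplotype step were tested on simulated data. Segments of 0.5, 0.7 and 1 in size were added to the residual noise of 3 arrays over 664420 autosomal probes. Of 72 segments of size 0.5, 71 were recovered in HAP line 1 (5 false calls over all sizes), 68 in HAP line 2 (1 false call) and 72 in H129 line 1 (0 false calls), and all 72 at sizes 0.7 and 1. Residual noise lacks the long trends of the arrays, so false calls on the arrays themselves may be more frequent. In the window test, 14, 47, 49 and 50 of 50 windows changed by 0.1, 0.2, 0.4 and 0.8 were recovered among 2413, with 9 unchanged windows called. Its noise was drawn independently for each array, so a signal shared between arrays was not simulated. In the haplotype step 841 of 841 windows were assigned rightly, in a simulation that used the CBA kidney signal itself and is therefore easy. The number of arrays limits the precision. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and BLAST 2.17.0.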

Results

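Genomic DNA of haploid mouse embryonic stem (ES) cells was compared with male kidney DNA on a tiling array for comparative genomic hybridisation, in which the sample (Cy3) and a reference (Cy5) compete for the same probes. Haploid ES cells carry a single set of chromosomes, and the study asked how their copy number differs across genetic backgrounds. The 8 arrays held 6 haploid lines and 2 kidney samples. HAP lines 1 and 2 (passages 25 and 18) came from a cross of CBA with B6 mice, HTG lines 1 and 2 (both at passage 11) came from a mixed transgenic strain, and H129 lines 1 and 2 (passages 17 and 12, each sorted 1 time) were set against 129/Sv kidney. The HAP and HTG lines, a CBA kidney and an HTG kidney were set against C57B/6 kidney. Each value is the log2 ratio of sample over reference at 1 of 713358 probes, centred here on the median of the 664420 autosomal probes of its array. Each line or kidney was measured on 1 array, so SD values given with a segment describe its probes, and the number of arrays limits the precision. Nothing in the labels beyond the line names says that samples came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The title of 1 H129 array names the other H129 line than its source label does, and the source label was followed here.

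The X chromosome stood above and the Y chromosome below the kidney level in all 6 haploid lines, and no whole autosome passed the threshold for a gain or loss. The median log2 ratio of X was 0.68 ± 0.07 (SD, n = 6) in the haploid lines and -0.01 ± 0.01 (SD, n = 2) in the kidneys, a difference of 0.69. A level of 0.68 is a 1.60-fold ratio to the male reference. The design expected a larger ratio, from 1 X per autosome set in haploid cells and 1 X per 2 sets in male kidney. Diploid cells with 2 X chromosomes also hold 1 X per autosome set, so the X level does not show that the cells were haploid. Y stood at -1.47 ± 0.27 (SD, n = 6) in the haploid lines and at -0.05 ± 0.03 (SD, n = 2) in the kidneys, and the unplaced Y sequence at -2.65 ± 0.20 and -0.10 ± 0.11. The medians of the 19 autosomes ran from -0.06 to 0.08 over the 6 haploid lines, and 0 autosomes passed the size threshold of 0.3. Exact two-sided permutation tests over the 28 splits of the 8 arrays gave p = 0.0714 for X, Y and unplaced Y sequence, also after Benjamini-Hochberg adjustment over the 3 tests, and 0.0714 is the smallest p this design can give. The differences of 0.69, -1.42 and -2.55 were larger than the spread within either group. HAP line 2 had the lowest X level, 0.54, against 0.69 to 0.74 in the other lines.

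**Figure D1:**
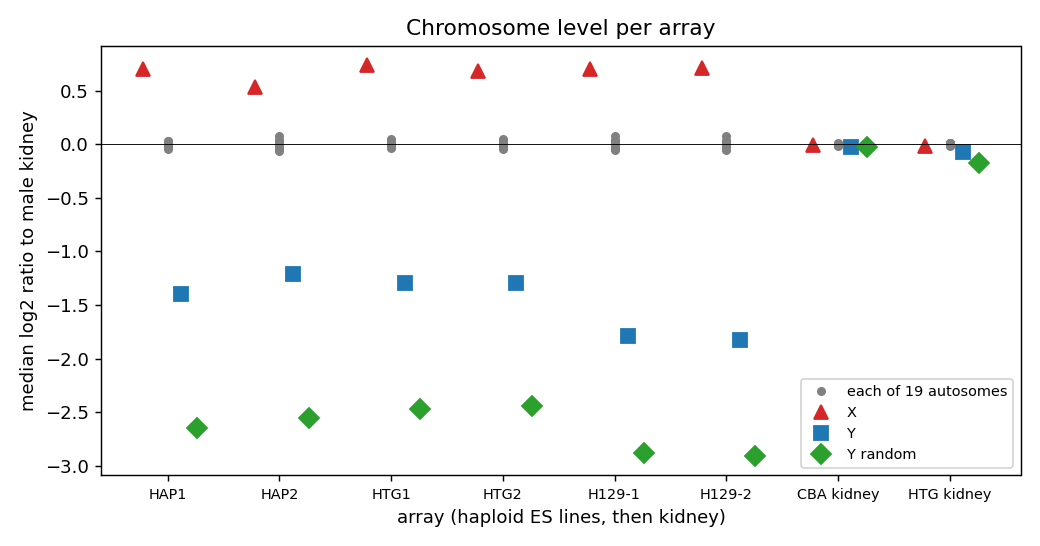
Median log2 ratio to male kidney (vertical axis) of each autosome, X, Y and the unplaced Y sequence (points) for each of the 8 arrays (horizontal axis). In the 6 haploid lines X lies between 0.54 and 0.74 and Y between -1.83 and -1.21, while the 2 kidneys average -0.01 for X and -0.05 for Y.

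Genes of both sex chromosomes followed the chromosome they lie on. The 12 X linked genes had a median of 0.78 in HAP line 1, 0.78 in HAP line 2 and 0.94 in H129 line 1, against -0.02 in the CBA kidney and 0.01 in the HTG kidney. Hprt, a purine salvage enzyme, stood at 0.80 in HAP line 1 and 0.78 in HAP line 2. Xist, the RNA that silences an X chromosome, stood at 0.25 in HTG line 2 and at -0.43 in the HTG kidney, below the other X linked genes of the same arrays. Among the 9 Y linked genes, Sry, the testis determining gene, stood at -2.18 in HAP line 1 and -2.53 in H129 line 1, and Uty at -1.24 and -1.79. The CBA kidney had Sry at 0.05 and Uty at -0.03. No gene of these lists lay in a called segment. Segments of X were called relative to the level of X itself, and no segments of Y are given.

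Called autosomal segments were mostly losses in the HAP and HTG lines and in both kidneys. A loss here means a low log2 ratio against the reference DNA. Probe sequences were not used, so a lower copy number was not separated from a sequence difference at the probes. This limit applies to each loss given below. HAP line 1 had 166 calls (130 losses), HAP line 2 had 66 (49 losses), HTG line 1 had 211 (137 losses), HTG line 2 had 240 (176 losses), the CBA kidney 161 (125 losses) and the HTG kidney 107 (71 losses). The deepest calls of HAP line 1 lay in the vomeronasal receptor cluster of chromosome 7, where Vmn1r101 (21019753 to 21060473) stood at -2.75 ± 0.41 (SD of 11 probes), with -2.47 in the CBA kidney and -0.09 in HAP line 2. The highest calls of 5 of these 6 arrays reached from 1.47 to 2.00 over Tmem181b-ps on chromosome 17, and in HAP line 1 the segment of Dynlt1b and Tmem181b-ps (6426155 to 6536181) stood at 0.94 ± 0.35 (SD of 32 probes). A gain of Glo1, a detoxifying glyoxalase, with Dnahc8 and Gm9874 (chromosome 17, 30586907 to 31057733) stood at 1.01 in HAP line 2 and 0.78 in the CBA kidney, against 0.05 in HAP line 1. All coordinates are in NCBIM37. No array comparison is tested here, because each line has 1 array, and the number of calls rose from 166 to 402 in HAP line 1 without winsorising of single probes.

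The lowest call of HAP line 2 (chromosome 1, 90835130 to 90869534) stood at -1.93 and held no coding gene. A call of chromosome 8 without coding genes (15426531 to 15481545) stood at -2.75 in HTG line 1 and -2.73 in HTG line 2. Among calls of 1 Mb or more, a segment of chromosome 1 (85337109 to 87557636) with Sp110 and Sp140 stood at -0.74 ± 0.35 (SD of 61 probes) in HAP line 2 and -0.72 in the CBA kidney, and at -0.05 in HAP line 1. Segments of chromosome 14 with Gm3127 and Gm3138 (4269994 to 5377378) stood at 0.72 in both HTG lines and 0.87 in the HTG kidney, and at 0.07 in the CBA kidney. HTG line 2 had a second chromosome 14 gain (6762002 to 8514304; Gm3366, Gm3494) at 0.66 and a chromosome 5 loss (94647153 to 95885259; Gm3106, Gm16522) at -1.40, which stood at -0.01 in HTG line 1 and -0.46 in the HTG kidney. The CBA kidney had losses of the Skint6 and Skint5 segment on chromosome 4 (-1.27), of chromosome 5 at Gm16427 (-0.73) and of chromosome 7 at Vmn1r124 and Vmn1r125 (-1.74), and the HTG kidney had calls over the last 2 of these (-0.42 and -1.15) and over the chromosome 14 genes (0.86 and 0.81).

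Most calls of the HAP and HTG lines were also present in the kidney of the same strain source, the comparison made in the study to separate differences of genetic background. A call counted as shared when the kidney had a median of the same sign and at least 0.2 in size over the same probes. The CBA kidney shared 150 of 166 calls of HAP line 1 (90.4%) and 65 of 66 of HAP line 2 (98.5%). The HTG kidney shared 165 of 211 calls of HTG line 1 (78.2%) and 197 of 240 of HTG line 2 (82.1%). The kidney of the other strain source shared fewer, 81, 38, 116 and 147 calls. Calls moved at random along the array were shared on average 3.20, 1.22, 3.08 and 3.79 times over 100 shifts. All these arrays used C57B/6 DNA as reference, so a copy number difference of the reference itself also counts as shared. With a stricter rule, in which a kidney call had to cover 0.5 of the call, the shares fell to 56.0%, 83.3%, 41.2% and 44.2%.

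**Figure D2:**
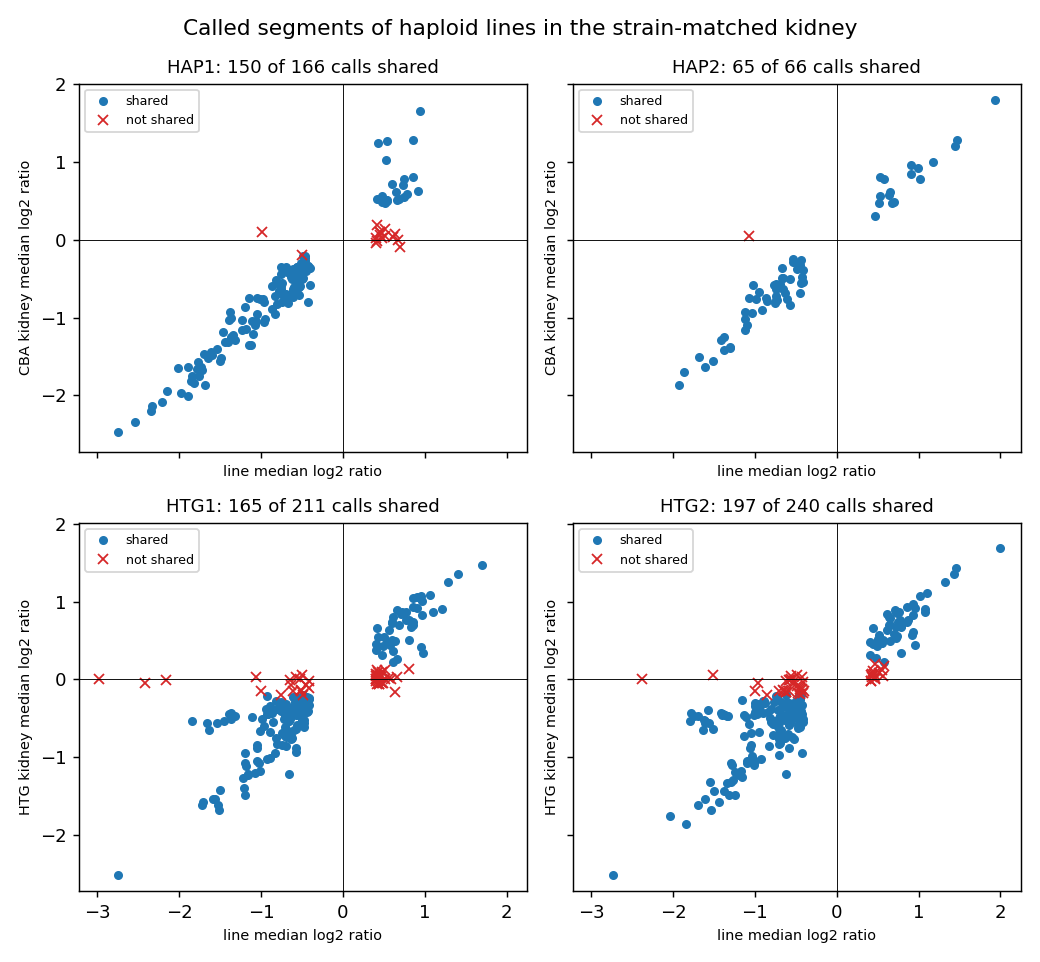
Median log2 ratio of each called segment in the haploid line (horizontal axis) and in the kidney of the same strain source (vertical axis), 1 panel per line, with shared calls as circles and others as crosses. The shared calls, 150 of 166, 65 of 66, 165 of 211 and 197 of 240, have the same sign in line and kidney, and the others lie near 0 in the kidney.

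The longest calls of HAP line 1 that its kidney lacked were gains. A segment of chromosome 1 (120505800 to 121004887) holding Tfcp2l1 (Tcfcp2l1 in the annotation), a transcription factor of naive pluripotency, and Gli2, a transcription factor of hedgehog signalling, stood at 0.67 ± 0.14 (SD of 143 probes), with 0.00 in the CBA kidney and 0.11 to 0.24 in the other 5 lines. A second segment of chromosome 1 (66521925 to 66875297) holding Unc80, Rpe and 1110028C15Rik stood at 0.70 ± 0.16 (SD of 100 probes), against -0.09 in the CBA kidney. A segment of chromosome 12 without coding genes (49781333 to 50145306) stood at 0.48 ± 0.19 (SD of 102 probes), against 0.03 in the CBA kidney. A segment of chromosome 17 holding Zfp960 and Zfp97 (17133069 to 17445818) stood at 0.45, but also at 0.88 in HTG line 1 and 0.70 in HTG line 2, and 1 of chromosome 12 (110392610 to 110547975) at 0.45, with 0.57 and 0.46 in the HTG lines. HAP line 2 had 1 call that its kidney lacked, a loss inside Nlgn1 on chromosome 3 (25419265 to 25456523) at -1.07 ± 0.57 (SD of 11 probes), which was low in all 6 haploid lines (-1.50 to -0.93). The chromosome 3 probes stood at 0.05 in the CBA kidney and -0.19 in the HTG kidney.

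**Figure D3:**
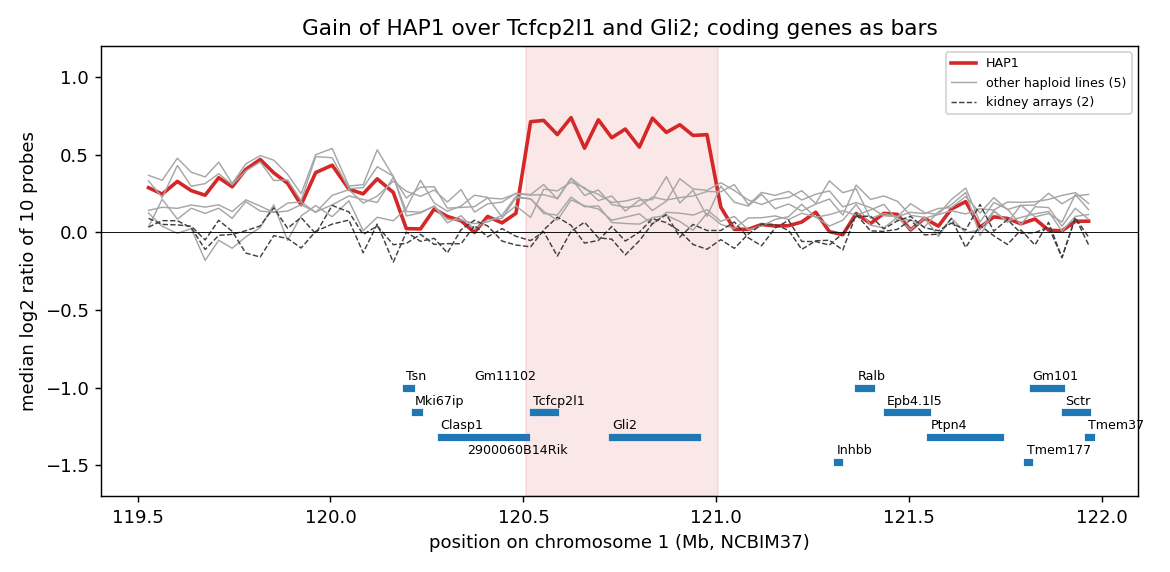
Median log2 ratio of 10 neighbouring probes (vertical axis) along chromosome 1 (horizontal axis, Mb) for HAP line 1, the other 5 haploid lines and the 2 kidneys, with coding genes as bars and the called segment shaded. HAP line 1 stands at 0.67 over Tcfcp2l1 and Gli2 and at 0.08 and 0.02 over the 50 probes on either side.

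The calls of the HTG lines that the HTG kidney lacked were gains and losses, 46 in line 1 and 43 in line 2. A part of Macrod2, an ADP-ribose hydrolase gene, on chromosome 2 (140646923 to 140726806) stood at -2.38 ± 0.68 (SD of 23 probes) in HTG line 2 and -2.42 in HTG line 1, against 0.00 in the HTG kidney. A part of Anks1b on chromosome 10 (89346802 to 89405866) stood at -2.42 ± 0.67 (SD of 18 probes) in HTG line 1, at 0.06 in HTG line 2 and at -0.05 in the HTG kidney. HTG line 2 alone had losses over the serine protease inhibitor genes Serpina1b, Serpina1d and Serpina1e on chromosome 12, the deepest (105157552 to 105196085) at -1.51 ± 0.72 (SD of 12 probes), and a gain over Crb2 on chromosome 2 (37536883 to 37655338) at 0.57. Its longest such call was on chromosome 19 (51894527 to 52126785), at -0.42. HTG line 1 had a loss of chromosome 4 (121408796 to 122203052) at -0.53, which stood at -1.49 in the CBA kidney, and 1 of chromosome 15 with Tas2r119 and Sema5a (31886922 to 32631934) at -0.42. This chromosome 15 segment also stood at -0.35 in HTG line 2 and at -0.26 and -0.25 in the H129 lines. Calls for which no other array had the same sign and at least 0.2 in size numbered 3 in HAP line 1 (Unc80, Sprr2a1 and the longer chromosome 12 gain), 0 in HAP line 2, 3 in HTG line 1 and 8 in HTG line 2. The Tfcp2l1 gain is not among them, as HAP line 2 and the H129 lines stood at 0.23 to 0.24 there. The HTG kidney, of a mixed strain, was measured on 1 array, and variants of that strain absent from this sample were not measured.

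The H129 lines, set against DNA of their own strain, had few calls. Each had 11 calls, 8 of them gains, and 10 calls of line 1 and 11 of line 2 had the same sign and at least 0.2 in the other line. The longest was the Dynlt1 and Tmem181 segment of chromosome 17 (6219081 to 6924388), at 0.50 ± 0.16 (SD of 188 probes) in line 1 and 0.54 in line 2, which also stood at 1.43 in HAP line 2 against the C57B/6 reference. Losses over Rsph3a and Rnaset2a (chromosome 17, 8145415 to 8359066) stood at -0.52 and -0.51, and those over Tagap1 and Rnaset2b (7143255 to 7336713) at -0.50 and -0.46. Sfi1 on chromosome 11 (3001561 to 3101853) stood at 0.69 and 0.72. Naip5 and Naip6, innate immune sensors of bacterial flagellin, stood at 0.58 in line 1 and 0.18 in line 2 (chromosome 13, 100992705 to 101129714), the call that line 2 lacked. The number of calls depended on the size threshold of 0.4, with 37 and 35 calls at 0.3 and with 5 and 4 at 0.6.

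The signal of the CBA kidney appeared in long blocks along the HAP lines, where each locus of a haploid line from a CBA by B6 cross carries 1 of the parental alleles. The correlation with the CBA kidney across probes was at least 0.5 in 23.5% of 1318 windows of 500 probes in HAP line 1 and 39.9% in HAP line 2, in 13.9% and 15.1% in the HTG lines and 26.1% in the HTG kidney, which share the reference DNA, and in 0.152% in each H129 line. A ratio chosen after seeing the data, the line's median over the CBA kidney's at probes low in CBA, lay between 0.3 and 0.7 in 1.19% of 841 informative windows in HAP line 1 and in 7.97% in HAP line 2. It had a median of 1.13 in the CBA-like windows and 0.01 in the others in HAP line 1, and 0.93 and 0.02 in HAP line 2. CBA-like windows made up 36.3% in HAP line 1, 49.8% in HAP line 2, 28.2% and 30.4% in the HTG lines, 29.4% in the HTG kidney and 0% in the H129 lines. HAP line 1 was CBA-like in at least 97.4% of the windows of chromosomes 9, 14, 15 and 18, and HAP line 2 in at least 96.2% of those of chromosomes 2, 3, 17 and 18. The blocks changed state 10 times in each HAP line when runs of a single window were left out. With them the changes numbered 25 and 34. Of the 10 changes in HAP line 1, 2 bounded a block of 2 windows on chromosome 12 (46849074 to 52313648) with a median ratio of 0.30, which holds the longer chromosome 12 gain. No test was run across windows, which are not replicates, and with Spearman correlations the share of HAP line 1 fell to 7.28%.

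**Figure D4:**
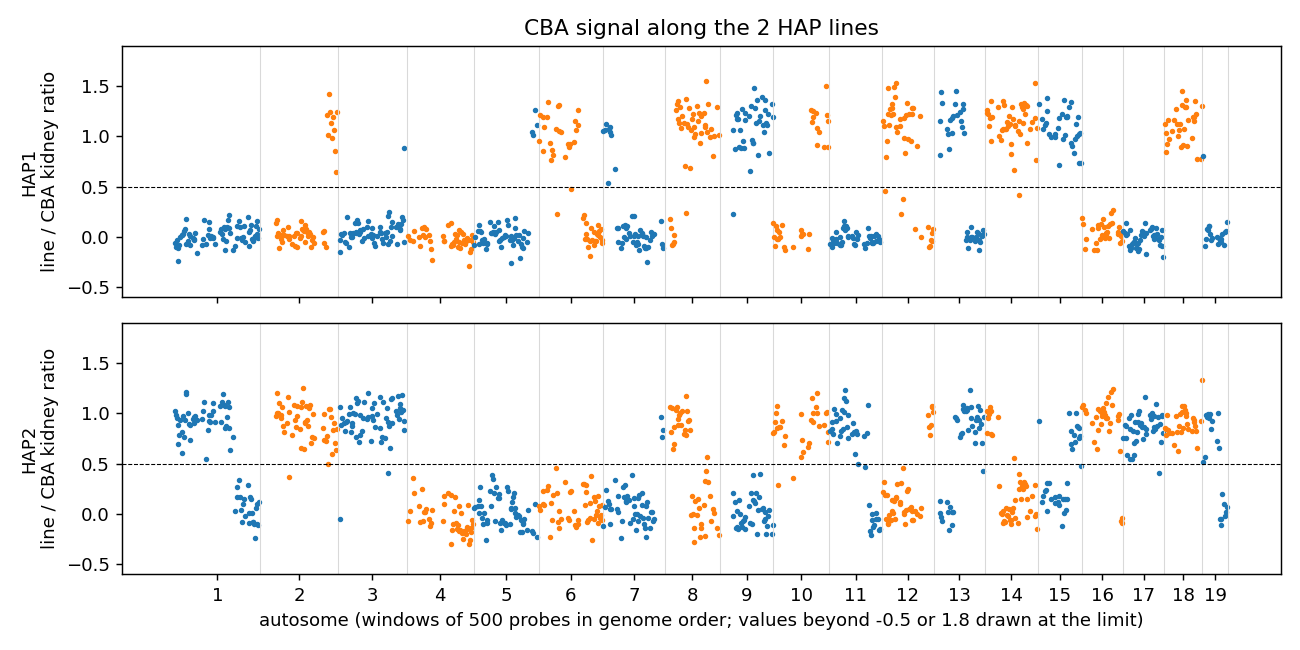
Ratio of the HAP line's median to the CBA kidney's over probes low in the CBA kidney (vertical axis) in windows of 500 probes in genome order (horizontal axis, autosomes), for HAP line 1 (upper panel) and HAP line 2 (lower panel). Windows gather near 1.13 and 0.01 in HAP line 1 and near 0.93 and 0.02 in HAP line 2, with the limit between the states at 0.5 (dashed).

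Windows of 1 Mb differed by small amounts between the haploid lines and kidney, and the difference went with the number of coding genes (r = 0.584 across windows, which are not independent, and 0.388 with GC content subtracted) and with GC content (r = 0.567). Among the windows past the adjusted p threshold, the largest negative difference was on chromosome 9 (28000001 to 29000000), where the 4 HAP and HTG lines stood at -0.20 ± 0.03 (SD, n = 4) and the 2 kidneys at 0.05 ± 0.01 (SD, n = 2), a difference of -0.25 (SE 0.03, limma adjusted p = 0.0167). The window of Cdh11, a cadherin, on chromosome 8 (105000001 to 106000000) differed by -0.24 (SE 0.03), and that of Lrrtm1 on chromosome 6 (77000001 to 78000000) by -0.23 (SE 0.03). The largest positive differences among these windows were 0.21 (SE 0.03) on chromosome 7 (46000001 to 47000000; Gm16387, Gm5114) and 0.19 (SE 0.05) on chromosome 4 (146000001 to 147000000; Zfp600). In the chromosome 7 window the lines stood at -0.01 ± 0.03 (SD, n = 4) and the kidneys at -0.22 ± 0.01 (SD, n = 2). This window lies in B6-like blocks of both HAP lines. A strain variant of the kidneys was therefore not separated there from a difference between haploid lines and kidney. A window of chromosome 7 with 69 coding genes, among them Vrk3, Atf5 and Nup62 (52000001 to 53000000), differed by 0.18 (SE 0.05, limma adjusted p = 0.0386). In each of these windows all 4 lines lay beyond both kidneys.

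Of 2413 windows, 144 were higher and 306 lower in the haploid lines at an adjusted p under 0.05 (limma), and 1009 had an unadjusted p under 0.05. The higher share was 32.0%, and 4.14% without centring of the arrays (24 higher and 556 lower). The counts rested on single arrays. In limma they were 0 and 0 without HTG line 2, without the CBA kidney or without the HTG kidney, when 754, 455 and 517 windows had an unadjusted p under 0.05. They were 8 and 121 without HTG line 1, 275 and 353 without HAP line 1, and 461 and 509 without HAP line 2. With the strain source as a block they were 64 and 238, and with the GC content of the windows regressed out, 332 and 440. The window levels went with GC content in HAP line 2 (r = 0.825) and in H129 line 1 (r = 0.751), less in HAP line 1 (r = 0.305) and hardly in the CBA kidney (r = 0.0341).

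Lists of genes fixed before the data were examined held most of their calls in strain-variable families and antigen receptor segments. These 2 lists hold 602 and 204 genes, against 9 to 23 in each other list. At an equal rate per gene most calls would also fall there. Of 20 pluripotency genes, 1 was gained, Tfcp2l1 in HAP line 1 (0.70 ± 0.17, SD of 22 probes), and Zfp42, the marker also called Rex1, lay in losses of HAP line 1, HTG line 1 and HTG line 2 (-0.56 ± 0.81, SD of 9 probes, -0.65 and -0.68), with -0.44 and -0.56 in the CBA and HTG kidneys, where it was not called. None of the 23 genes of growth and genome guard lay in a call, Trp53 standing at 0.04 in HAP line 1 and 0.28 in HAP line 2, nor did any of the 20 imprinted genes, of which H19 stood at 0.12 and Igf2 at 0.01 in HAP line 1. Of 602 strain-variable genes 585 had enough probes. They held 43 losses and 6 gains in HAP line 1, 22 and 1 in HAP line 2, 55 and 27 in HTG line 1, 77 and 19 in HTG line 2, 79 and 14 in the CBA kidney and 76 and 14 in the HTG kidney, and in the H129 lines 0 losses, with 3 gains in line 1 and 0 in line 2. Of 204 antigen receptor segments, listed because kidney can hold lymphocytes, 25 lay in losses in HAP line 1, 15 in HAP line 2, 20 in HTG line 1, 33 in HTG line 2, 40 in the CBA kidney, 25 in the HTG kidney and 0 in the H129 lines. Gains held 5 of these segments in HTG line 2, 3 in the CBA kidney, 1 in the HTG kidney and 0 in the other arrays. No p-value is given for a list, as each array stands alone.

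The families with losses differed between the HAP lines, along the blocks given above. The Vmn1r cluster of chromosome 7 was CBA-like in HAP line 1 and B6-like in HAP line 2. Chromosome 8 at Defa20 and chromosome 17 were the reverse, and chromosome 4 was B6-like in both. Of the CBA kidney calls, 98.4% and 98.3% in CBA-like parts were present in HAP lines 1 and 2, against 8.16% and 12.7% in B6-like parts. Part of this is built in, as the state rests on probes low in that kidney. As above, a loss is a low log2 ratio, and a sequence difference at the probes was not separated from a lower copy number. Of 237 entries of the Vmn1r vomeronasal receptor family, pseudogenes included, 43 were lost in HAP line 1, 0 in HAP line 2, 44 in the CBA kidney, 41 and 43 in the HTG lines and 46 in the HTG kidney. Of 29 entries of the Defa family of intestinal defensins, pseudogenes included, 19 were lost in HAP line 2, 0 in HAP line 1, 17 in the CBA kidney, 0 in HTG line 1, 17 in HTG line 2 and 19 in the HTG kidney. In the H2-Q family of the major histocompatibility complex, 3 of 6 genes were lost in HAP line 2 and in the CBA kidney, and 2 were gained in HTG line 2 and in the HTG kidney. Of 11 Skint genes, 6 were lost in the CBA kidney, 5 in each HTG line, 3 in the HTG kidney and 0 in either HAP line. Among the antigen receptor segments, 25 of 45 Trav segments were lost in HAP line 1, in HTG line 2 and in both kidneys and 20 in HTG line 1, and 15 of 37 Ighv segments in HAP line 2 and in the CBA kidney and 8 in HTG line 2.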

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

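The test of a strain variant on chromosome 3 and all tests of the HAP line 1 gains were chosen after the values they use had been seen, as was the GC-subtracted X level, and the other tests of this part before. Of 11 groups of haploid values examined for a sample far from the others, 1 had one, and chance gives about 1 in 20. The X level of HAP line 2 (0.54) lay below those of the other 5 lines (0.69 to 0.74), with a gap of 0.758 of the whole range, and after the GC trend of the windows was subtracted it was 0.62 against 0.75 to 0.79 (0.727 of the range). Over the list of X linked genes HAP line 2 was not set apart. Its median was 0.778, against 0.781 to 0.946 in the other 5 lines (0.0178 of the range). The ES minus kidney difference was higher in HAP than in HTG in 3 windows of chromosome 4 by an interaction term in limma with 2 residual degrees of freedom. Each kidney in it is 1 array and was assumed to vary like the lines. The windows started at 42000001 (1.11 higher, adjusted p = 0.0413), 112000001 (1.70, adjusted p = 6.65e-05) and 113000001 (1.36, adjusted p = 0.000513), the last 2 holding Skint genes, and 11 windows had an unadjusted p under 0.05. In the window from 112000001 the HAP lines stood at 0.01 and -0.13, the CBA kidney at -1.10, the HTG lines at -1.08 (both) and the HTG kidney at -0.41. Of 46 informative windows of chromosome 4, 0 were CBA-like in either HAP line.

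The chromosome 3 segment inside Nlgn1 was low in all 6 haploid lines (-1.50 to -0.93) and stood at 0.049 (SE 0.06) in the CBA kidney. It was picked because that kidney lacked it. The outcome of the strain variant test on that kidney was therefore fixed, and it decides nothing about the segment. Unplaced contigs of the reference matched 99.7% of its bases, against a median of 8.73% and at most 55.8% for 200 random segments, and 90.9% of its probe sites, against 0.831%, whereas the placed Y, of which 13.2 of 15.9 Mb is gap, matched 0.392%. None of the 6 long-matched contigs held a transcript found only on Y (0%), a result that had been written beforehand as evidence against Y contigs and was set aside after it was seen, because only 1 of 183 other contigs held one, so the test had no power. Both contig matches met what had been written for Y sequence, and were then lowered to undecided because the chromosome of these contigs is not stated in the reference. A copy of the segment on the male reference's Y may account for the loss, but it cannot be told apart from other differences between the lines and kidney. Of biological explanations only a strain variant and Y sequence were tested, and neither test could decide. The H129 lines stood at -1.49 ± 0.54 and -1.50 ± 0.62 (SD of 11 probes) against kidney DNA of their own strain. For these 2 lines that argues against a strain variant. The unplaced contigs hold 62.1 Mb and the unplaced Y sequence of the provider files 58682461 bases, but a similar length does not assign the matched contigs to Y.

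A linear GC trend did not alone account for the autosomal windows that differed between haploid lines and kidney. With it regressed out, 382 of 450 (84.9%) remained past the threshold. The median size of the 450 fell from 0.14 to 0.10 and 1 window changed sign. Over all windows, counts rose from 144 higher and 306 lower to 332 and 440, so a kept call can reflect a smaller spread. Other forms of a GC effect were not tested. With GC subtracted, the mean of the 2 H129 arrays, from another provider and reference, correlated with the ES minus kidney difference at r = 0.860 across 2413 windows (0.827 to 0.896 by a bootstrap over chromosomes). A source common to haploid ES cells, such as DNA replication in cycling cells, is a hypothesis in line with this. A difference between DNA from cultured cells and from kidney in its preparation follows the same groups, was not tested and stays open. No window passed the threshold without HTG line 2 or without either kidney (0 each), so the windows called rest on few arrays.

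The gains of HAP line 1 on chromosomes 1 and 12 exceeded the median of the other 5 lines by 0.80 ± 0.44, 0.47 ± 0.13 (chromosome 1) and 0.61 ± 0.18 (chromosome 12, SD over probes) inside the segments. The chromosome 17 gain exceeded that median by 0.032. These segments were grouped after the levels of the other lines had been seen. The outcome of the test of a shared trend or variant was therefore fixed, and it decides nothing about a cause. An extra copy in most cells of the line is a hypothesis for the gains on chromosomes 1 and 12. Their levels were 0.67 and 0.70 on chromosome 1 and 0.48 on chromosome 12, against 0.71 on X in this line. The excess beyond an edge reached 0.19 (SE 0.11), above the limit of 0.15 written for that test, and this was called undecided only after a term for its spread had been added. This was at the Unc80 segment of chromosome 1. Beyond its edges HAP line 1 itself stood at -0.002 and 0.093, so the excess there was larger than the line's own level. By that test an extra copy cannot be told apart from other sources of a raised signal. Chromosome 1 of HAP line 1 held 0 CBA-like windows of 74, and no independent sample of this line or of its parents was measured.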

How the results depend on the processing

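Added after seeing the data were the ratio to the CBA kidney, the raw and spatially corrected H129 ratios, the joining of neighbouring calls and the GC-subtracted X and autosome levels. Of 208 alternatives 131 left a result on its side of the threshold or within its spread or 1.5 times its count, 77 moved it and 0 reversed it. All 40 alternatives for X and Y, 3 for whole autosomes and 7 for gene lists were among the 131, though no test of X or Y could reach the threshold. The numbers of calls at a penalty factor of 8 were 87 (HAP line 1), 40 (HAP line 2), 96 (HTG line 1), 113 (HTG line 2), 93 (CBA kidney) and 63 (HTG kidney), and without winsorising 402, 129, 565, 595, 289 and 218. At a threshold of 0.6 they were 103, 123 and 153 in HAP line 1 and the HTG lines. H129 lines had 37 and 35 calls at 0.3, 5 and 4 at 0.6, and line 1 had 17 with the raw ratio. Shares of calls found in the matched kidney (HAP line 1, HAP line 2, HTG line 1, HTG line 2) were 83.4%, 87.8%, 58.8% and 74.2% at a threshold of 0.3, 56.0%, 83.3%, 41.2% and 44.2% with a kidney call over 0.5 of the length, and 74.7%, 86.4%, 58.8% and 62.5% with a kidney median of 0.4. At 0.6 they were 95.1%, 90.2% and 92.8% in HAP line 1, HTG line 1 and HTG line 2. HAP line 2 had 100% with 20 probes and with a penalty factor of 8, where the HTG lines had 84.4% and 91.2%, and with means of probes the HTG lines had 68.0% and 73.8%. The share of windows with a correlation of at least 0.5 to the CBA kidney in HAP line 1 (23.5%) was 20.3% with windows of 200 probes and 26.4% with the longest windows tried, and 7.28% with Spearman correlations. The added ratio, another measure over other windows, gave 36.3% CBA-like windows in HAP line 1 and 49.8% in HAP line 2. Higher and lower windows numbered 483 and 531 with the H129 arrays, 64 (higher) with the strain block, 233 and 576 at 500 kb, 66 and 142 at 2 Mb, 24 and 556 without centring and 332 (higher) with GC regressed out. Leaving out 1 array gave from 0 to 461 higher and from 0 to 509 lower windows, where a lone kidney was assumed to vary like the lines. Smaller windows and fewer arrays change the number tested or the power by construction, and otherwise the cause was not tested. The alternative with the provider's segments was not run, because the files used hold no segments. No paired analysis was possible because the kidney groups hold only number 1, so that groups share fewer than 2 replicate numbers, and the numbers name different lines. The fit with the strain source as a block (64 higher, 238 lower) matches lines and kidneys by source, not by number. Signal over background was not computed, and the number of arrays limits what can be called.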

Other observations

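The counts of this part were chosen after seeing the data. Deep losses (at most -1) shared with the kidney were of similar size in line and kidney for the HAP lines, where the kidney had a median of 0.922 ± 0.116 (SD over losses) of the size in HAP line 1 (51 losses) and 0.918 ± 0.131 in HAP line 2 (17 losses), and 0 losses lay under 0.5 of it. For the HTG lines 10 of 33 losses (30.3%) in line 1 and 21 of 51 (41.2%) in line 2 stood in the HTG kidney at under 0.5 of their size in the line, while the medians over all these losses were 0.923 ± 0.316 and 0.826 ± 0.326. An example was the Trim34a, Trim5 and Trim12a segment of chromosome 7 (111409197 to 111478962), at -1.85 in HTG line 1, -1.79 in HTG line 2 and -0.54 in the HTG kidney.

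Lines of one source differed in how many calls they had in common. Of the calls of HAP line 1, 51 of 166 (30.7%) were present in HAP line 2, and 20 of 66 (30.3%) the other way. Of the calls of HTG line 1, 195 of 211 (92.4%) were present in HTG line 2, and 187 of 240 (77.9%) the other way. The probe values of the HTG lines correlated at r = 0.772, those of the HAP lines at 0.278 and those of the H129 lines at 0.687, across probes, which are not independent replicates. On X, segments called relative to the chromosome numbered 33 in HAP line 1, 12 in HAP line 2, 16 and 17 in the HTG lines, 12 and 17 in the H129 lines, 9 in the CBA kidney and 5 in the HTG kidney. The segment at the start of X (3000121 to 4292876, with Gm14346) stood above the rest of X by 0.44 in HAP line 1, 0.48 in the CBA kidney and 0.43 in the HTG kidney, and at -0.11 in H129 line 1. Many X calls of the haploid lines lay between 120112979 and 122712817. A segment with Gm17503 (120275748 to 120358244) stood at -2.01 and -1.30 in the HAP lines and -1.09 and -1.02 in the HTG lines. It stood at -1.545 and -1.486 in the H129 lines, -0.44 in the CBA kidney and -0.09 in the HTG kidney. A call inside this range (120223404 to 120274002) differed, at 0.145 in HTG line 1 and -0.834 in the CBA kidney. The cause of these low values was not tested.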
